A study of Mus musculus with 6 samples.

How the data were processed

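RNA sequencing of 6 samples of mouse calvarial osteoblasts was used, 3 cultured without and 3 with 10 μM ZM for 6 days in osteogenic induction medium. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with an mRNA library kit. The submitters' processing notes name HISAT2 2.2.1, featureCounts 2.0.3 of the Subread package, DESeq2 and the genome build mm10. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here.

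The deposited table lists a read count and an FPKM value for 31401 genes in each sample, per the file headers. The counts deposited by the authors are whole numbers and were not normalized. The FPKM values deposited by the authors equal the count divided by the library's column total and by a fixed gene length, which came out as a whole number of bases (within 0.01) for 100% of genes. That length equalled the joined exon length in GENCODE M21 for 98.2% of the genes found there, so it includes untranslated regions. Of the listed gene IDs 30765 are in GENCODE M21, and 249 rows carry no gene symbol. These rows have gene IDs and stayed in library sizes and tests. Coordinates are from GENCODE M21 on GRCm38, the assembly also called mm10, and are 1-based.

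Library totals were 42721326 to 69867931 counts. A gene with 0 counts in a library may have a level of up to 3 counts there, or 0.0429 to 0.0702 CPM, which covers counting error only. Pairs of libraries of a group differed beyond sampling noise over genes with counts (chi-square per degree of freedom 5.71 to 9.79), so no library was taken as a copy of another. This does not show that they are separate cultures.

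Genes passing edgeR's expression filter (17533) were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the robust quasi-likelihood F test and Benjamini-Hochberg adjustment at a threshold of 0.05. The fit held the 2 groups only. The biological coefficient of variation was 6.46%. CPM values come from the cpm function of edgeR on TMM-scaled library sizes. Standard errors of log2 fold changes are the absolute fold change divided by the square root of F.

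The 39 gene lists, covering bone cells, the signalling ZM is known to inhibit, stress, metabolism and other cell types, were written before the data were examined, as were the choice of tests, the alternatives and the rule for named genes. Of these, 38 had the 5 tested members needed for camera (limma 3.58.1), a competitive set test on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and 19 passed (5 up, 14 down). With an estimated correlation 0 of the 38 passed at the adjusted threshold, and fry, a self-contained test of whether a list's genes move one way on balance, called 30. List symbols absent from the table were looked up among RefSeq synonyms.

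Named genes are the 12 with the largest rise and the 12 with the largest fall among genes past the threshold whose groups do not overlap and whose higher group mean is at least 5 FPKM, with predicted genes left out (1 among the falls), up to 2 risen and 2 fallen members of each list, and a fixed set of bone, VEGF, EGF and proliferation genes. Of the fixed set, Bglap, Dmp1 and Cyp1a1 fell below the filter, and Sost was not analysed here. Other genes are said to be chosen after their values were seen.

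Alternatives were a replicate block, leaving out each sample in turn, DESeq2 1.42.0, other scalings and filters, limma-trend on log2(FPKM + 1) for genes with a mean FPKM of at least 1, a minimum fold change and glmTreat against 1.5-fold. The pseudocount of 1 understates changes of low genes on that scale.

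The tests were checked on simulated data, with counts drawn for the real genes at the real depths and 50 genes changed at each of 4 sizes. For ZM against control edgeR, over 17280 genes, recovered 20 of 50 genes at 1.2-fold, 41 at 1.5-fold, 41 at 2-fold and 50 at 4-fold, and 4.40% of its calls were false. In this 1 simulated data set false calls were 12.5% for DESeq2 and 7.87% for limma on log2(FPKM + 1), above the threshold of 0.05. A call that only these make is therefore taken as weaker. Camera called 10 of 10 shifted and 0 of 100 unshifted lists. The simulated genes varied independently of each other, and far fewer of them changed than in the data. Their spread followed the trend with expression level, without spread particular to a gene. The ranking of the methods may therefore not carry over to the data. Members of a real list can vary together, with an estimated correlation of up to 0.92, so this check could not show false list calls from that.

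The longest transcript of each list or named gene was compared with all other annotated transcripts by BLAST+ 2.17.0 (at least 97% identity over at least 100 bases), and exon overlaps were taken from GENCODE M21. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart. Named genes with at least 10% of their exon bases or transcript shared in this way are given as uncertain. This limit was set after the values were seen.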

Results

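mRNA sequencing libraries were made from primary osteoblasts, the bone-forming cells, grown out of mouse calvaria (the flat skull bones). The cultures spent 6 days in osteogenic induction medium either without ZM (control, 3 samples) or with 10 μM ZM (3 samples). ZM is ZM-306416, a small molecule known as an inhibitor of VEGF receptors and of the EGF receptor. All 6 samples carry the same batch label. The series title asks about bone loss, bone formation and osteoclast formation, and the comparison here addresses which genes of the osteoblast cultures differ with ZM. Total counts per library were 42721326, 69867931 and 62191251 in control samples 1 to 3 and 57020669, 44714005 and 48768462 in ZM samples 1 to 3, with 24067 to 25681 genes detected by at least 1 count. No label says whether the 3 samples of a group are separate cultures, so the p-values measure only the spread between these samples, which may be technical.

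With ZM, the cultures held more of the transcripts of the bone alkaline phosphatase Alpl (11.9-fold), the vitamin D receptor Vdr (4.24-fold) and the osteoclast genes Mmp9 (10.2-fold), Acp5 (9.93-fold) and Dcstamp (16.4-fold). They held less of the osteopontin transcript Spp1 (3.13-fold lower), the angiogenic factor Vegfa (3.46-fold lower), the interleukin Il1a (23.0-fold lower) and the prostaglandin synthase Ptgs2 (6.29-fold lower). Genes read out of ERK signalling, sterol synthesis and macrophages were lower as groups, and genes of osteoblast commitment, BMP response, Wnt response, insulin-like growth factors and osteoclasts were higher as groups (camera). With an estimated correlation between members 0 of these 8 list calls passed (adjusted p = 0.14 to adjusted p = 0.30). Col1a1, the main collagen chain of bone, was at 8890 ± 356 CPM (counts scaled to library size; SD, n = 3) in control and 8774 ± 271 (SD, n = 3) in ZM samples, which did not differ beyond the spread (adjusted p = 0.70, edgeR).

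By edgeR's quasi-likelihood test, 7939 of 17533 tested genes differed between the groups, 4004 higher and 3935 lower with ZM. Of these, 1329 differed at least 2-fold (582 higher, 747 lower) and 2740 by less than 1.2-fold. The groups did not overlap in 54.2% of tested genes, where chance gives 10% for 3 samples against 3. With scaling by library size alone 62.2% of the called genes were higher, against 50.4% with TMM scaling, and on the deposited FPKM values 62.8% were higher, so the balance between higher and lower calls depended on the scaling. Correlations of log2 CPM were 0.992 to 0.994 within groups and 0.977 to 0.979 between them.

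Osteoblast commitment genes rose. Of 14 tested members of that list 11 rose and 1 fell, with the same counts adjusted over the list alone (set test adjusted p = 2.2e-05; adjusted p = 0.19 with an estimated correlation). Alpl (chromosome 4, 137741733 to 137796384, minus strand, mm10), which frees phosphate for mineral, went from 2.60 ± 0.28 to 30.9 ± 0.955 CPM (SD, n = 3 each), a log2 fold change of 3.58 ± 0.08 (SE). Vdr rose by 2.08 ± 0.05 on the log2 scale, the osteoblast transcription factor Sp7 by 0.85 ± 0.18 and its upstream factor Runx2 by 0.29 ± 0.05. Sp7 was low in both groups, at 1.38 CPM in control and 2.48 CPM in ZM samples. The member that fell was the BMP receptor Bmpr1b, with a log2 fold change of -1.05 ± 0.08.

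Genes of mineralisation and late osteoblasts moved the other way as a list. Of 16 tested members 8 fell and 3 rose, also when adjusted over the list alone (set test adjusted p = 0.0057; adjusted p = 0.19 with an estimated correlation). The pyrophosphate-generating enzyme Enpp1 went from 152 ± 6.73 to 40.0 ± 0.911 CPM, a log2 fold change of -1.93 ± 0.04. The endopeptidase Phex, known for its part in phosphate balance, was low and fell from 0.898 to 0.194 CPM (log2 fold change -2.23 ± 0.36). Enpp1 is known as a brake on mineral growth, so the list is mixed and its fall cannot be read as less mineralisation. Matn4 (2.68 ± 0.10) and osteomodulin, Omd (1.97 ± 0.28, from 0.397 to 1.61 CPM), rose. Spp1 (chromosome 5, 104435118 to 104441050), also made by macrophages, was the transcript of second-highest count in each control library and stood at rank 13 or 14 in each ZM library. Its level was 15169 ± 454 CPM in control and 4853 ± 255 CPM in ZM samples. Bone sialoprotein, Ibsp, was near the floor in both groups (0.142 and 0.236 CPM, adjusted p = 0.22), and osteocalcin, Bglap, had 4, 9 and 8 counts in the control and 6, 2 and 2 in the ZM samples. The Bglap transcript matches the neighbouring Bglap2 over 99.8% of its length, so reads shared by both may be missing from its count. Dmp1 had 8 counts in control sample 3 and 0 in the others, where 0 counts allow up to 0.0702 CPM at the depth of the shallowest library. Of the osteocyte list 3 of 9 tested members rose and 5 fell, among them Ptprz1 (1.86 ± 0.06) and the podoplanin gene Pdpn (-1.06 ± 0.07), and the list did not pass its set test (adjusted p = 0.43).

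**Figure D1:**
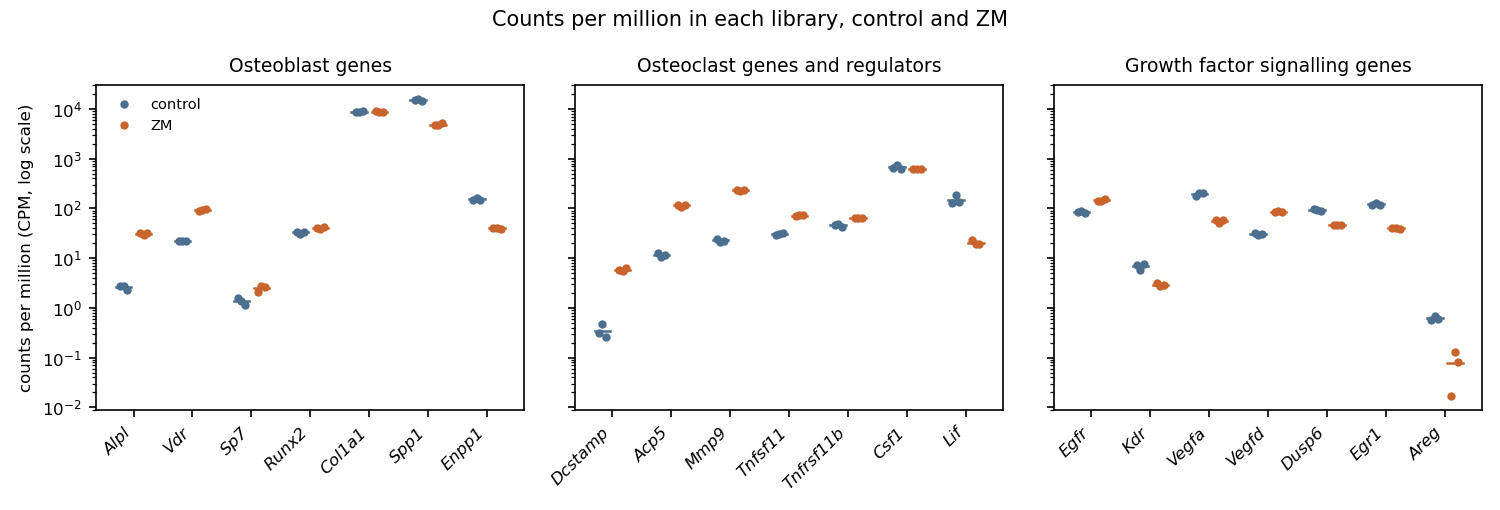
CPM (TMM-scaled, log axis) of named genes in each of the 3 control (blue) and 3 ZM (orange) libraries; points are libraries and bars the group means. Alpl sits near 2.60 CPM in control and 30.9 CPM in ZM samples, Spp1 is lower with ZM and the Col1a1 groups overlap.

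The matrix genes split. Among fibrillar collagens and their processing and crosslinking enzymes 15 of 31 members rose and 10 fell (16 and 11 adjusted over the list alone), with no shift of the list (set test adjusted p = 0.43). The procollagen protease Adamts2 (0.91 ± 0.04) and the prolyl hydroxylase P4ha2 (0.81 ± 0.04) rose, and Col5a3 (-1.16 ± 0.04) and Loxl3 (-0.68 ± 0.04) fell. Of 22 matrix proteases and inhibitors 11 rose and 10 fell (11 and 11 adjusted over the list alone; set test adjusted p = 0.86, with a median of 0.02, a mean of -0.10 and a test direction upward; fry adjusted p = 0.0028). Mmp9 and the aggrecanase Adamts5 (2.15 ± 0.04) rose, while the stromelysin Mmp10 went from 24.2 ± 1.71 to 0.831 ± 0.199 CPM and the urokinase Plau fell by 1.82 on the log2 scale.

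Osteoclast genes rose in these osteoblast cultures. Of 15 members 11 rose and 1 fell, also when adjusted over the list alone (set test adjusted p = 6.05e-06; adjusted p = 0.19 with an estimated correlation). Dcstamp, needed for fusion of osteoclast precursors, went from 0.348 ± 0.110 to 5.86 ± 0.408 CPM, and its partner Ocstamp from 0.182 ± 0.054 to 2.15 ± 0.424 CPM. The tartrate-resistant phosphatase Acp5 went from 11.6 ± 0.954 to 115 ± 4.59 CPM and Mmp9 (chromosome 2, 164940780 to 164955850) from 22.8 ± 1.47 to 232 ± 7.47 CPM. The proton pump subunit Tcirg1 was the member that fell, by 0.11 ± 0.03 (SE) on the log2 scale. Its call ended with scaling by library size alone (adjusted p = 0.21), on FPKM (adjusted p = 0.16) and without ZM sample 2 (adjusted p = 0.052). Macrophage markers, of the lineage osteoclasts come from, were lower in the same libraries, with Itgam at 118 ± 3.93 CPM in control and 55.0 ± 4.73 CPM in ZM samples.

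Among genes by which osteoblasts regulate osteoclasts, 7 of 20 rose and 9 fell (8 and 11 adjusted over the list alone; set test adjusted p = 0.43). The RANK ligand gene Tnfsf11 (chromosome 14, 78277445 to 78308043) rose 2.34-fold, from 30.7 ± 1.22 to 72.0 ± 2.31 CPM, and the decoy receptor Tnfrsf11b 1.41-fold, from 45.5 ± 2.59 to 64.3 ± 1.12 CPM. The Tnfsf11 level was 67.6% ± 6.50 of the Tnfrsf11b level in control and 112% ± 4.75 in ZM samples (SD, n = 3 each), with each ZM sample above each control sample. CPM values are not corrected for gene length, so the ratio itself depends on the lengths of both genes and only its difference between the groups can be read. An exact two-sided permutation test gave p = 0.1 for this ratio, the smallest that 3 samples against 3 allow. Csf1 was at 675 ± 56.7 and 616 ± 10.7 CPM (adjusted p = 0.059), and passed the threshold without control sample 3 (log2 fold change -0.18, adjusted p = 0.0058). It also passed with DESeq2 (adjusted p = 0.022), a replicate block (adjusted p = 0.044), a mean of at least 1 CPM (adjusted p = 0.043) or no filter. Wnt16 (2.90 ± 0.24) and Sfrp1 (2.30 ± 0.05) rose, while the cytokines Lif (-2.88 ± 0.20) and Il11 (-2.73 ± 0.20) fell. Of these, Wnt16 (0.260 to 1.94 CPM) and Il11 (3.18 to 0.481 CPM) were low.

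Macrophage and haematopoietic markers were lower with ZM. Of 18 members 16 fell and 1 rose, also when adjusted over the list alone (set test adjusted p = 7.97e-08; adjusted p = 0.30 with an estimated correlation). The invariant chain Cd74 fell by 1.17 and the integrin Itgam by 1.10 on the log2 scale, and the fractalkine receptor Cx3cr1 rose, from 8.95 ± 1.43 to 16.2 ± 0.713 CPM. Exons of Itgam overlap another annotated gene over 68.7% of their length, so its level is uncertain. The lysozyme gene Lyz2, chosen after its values were seen, held 1.61% ± 0.03 of all counts in control and 0.884% ± 0.05 in ZM samples (SD, n = 3 each) and ranked first in every control library. Lysosome and autophagy genes fell with them: 18 of 25 members were lower and 4 higher, also over the list alone, by small amounts (median -0.15; set test adjusted p = 0.0016; adjusted p = 0.38 with an estimated correlation). Cathepsin D, Ctsd (-0.61 ± 0.04), and Gpnmb (-0.52 ± 0.03), both abundant in macrophages, fell, and Ulk1 (0.23 ± 0.04) and Wipi1 (0.22 ± 0.04) rose. Ctsd exons overlap another annotated gene over 34.4% of their length, so its level is uncertain.

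Inflammatory cytokines and chemokines went both ways while 16 of the 18 macrophage markers were lower. Of 21 members 9 fell and 4 rose (11 and 5 adjusted over the list alone; set test adjusted p = 0.049; adjusted p = 0.68 with an estimated correlation). Ptgs2 went from 637 ± 30.6 to 101 ± 4.12 CPM and Il1b from 2.39 ± 1.35 to 0.147 ± 0.0641 CPM, while the acute-phase gene Saa3 went from 2100.4 ± 248 to 5850.4 ± 578 CPM and the chemokine Cxcl5 rose 2.87-fold. The list's call ended without control sample 2 (adjusted p = 0.14) and without ZM sample 3 (adjusted p = 0.08), with RLE size factors (adjusted p = 0.053), at a mean of at least 1 CPM (adjusted p = 0.073) and on FPKM (adjusted p = 0.13). Interferon-stimulated genes were lower in the set test (adjusted p = 0.011; adjusted p = 0.66 with an estimated correlation, which was 0.92), but only Bst2 and Oas1a of 24 members fell over all genes tested, and 0 passed adjusted over the list alone (edgeR; 2 over all genes). The lower level was in 2 of the 3 ZM libraries: the mean log2 CPM of the list, relative to the mean of all 6 libraries, was 0.58, 0.29 and 0.10 in control samples 1 to 3 and -0.83, 0.57 and -0.71 in ZM samples 1 to 3. The Oas1a transcript matches Oas1g over 100% of its length. The Bst2 call ended without any of the control samples or ZM sample 1 (adjusted p between 0.055 and 0.072) and with a replicate block (adjusted p = 0.058). That of Oas1a ended without any sample except ZM sample 2 (adjusted p between 0.069 and 0.13), with a replicate block (adjusted p = 0.15) and without a filter on low counts (adjusted p = 0.084). The interferon call ended without control sample 1 (adjusted p = 0.06), ZM sample 1 (adjusted p = 0.11) or ZM sample 3 (adjusted p = 0.072), and with DESeq2 (adjusted p = 0.42) and fry (adjusted p = 0.27).

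The ligands and receptors of the pathways ZM is known to inhibit were mixed. Of 16 VEGF and PDGF ligands and receptors 6 rose and 7 fell, also over the list alone, with no shift of the list (set test adjusted p = 0.79). Vegfa (chromosome 17, 46016993 to 46032369) went from 196 ± 15.6 to 56.6 ± 4.54 CPM and the receptor Kdr from 6.93 ± 0.928 to 2.92 ± 0.222 CPM, while Vegfd (1.49 ± 0.05) and Pdgfd (1.97 ± 0.06) rose. Flt1 was at 0.945 and 1.24 CPM (adjusted p = 0.17). In the EGF family 6 of 16 members rose and 7 fell, also over the list alone (set test adjusted p = 0.41; adjusted p = 0.048 with DESeq2; fry adjusted p = 0.0036). The receptor Egfr rose 1.75-fold, from 84.5 ± 2.93 to 148 ± 6.55 CPM. The ligands Areg (-3.06 ± 0.48) and Epgn (-3.15 ± 0.35) fell, Tgfa (1.25 ± 0.34) and Erbb4 (2.32 ± 0.57) rose, and all 4 stayed below 2 CPM.

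Genes transcribed in response to ERK signalling, which acts downstream of both receptor families, fell. Of 25 members 19 fell and 3 rose (20 and 3 adjusted over the list alone; set test adjusted p = 6.8e-07; adjusted p = 0.14 with an estimated correlation). The immediate-early factors Egr1 (-1.60 ± 0.05) and Egr3 (-2.91 ± 0.14) fell, as did the ERK phosphatase Dusp6, from 91.7 ± 4.62 to 46.3 ± 0.479 CPM. Spry1 (0.86 ± 0.09) and Epha4 (0.79 ± 0.04) rose.

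BMP response genes rose, 14 of 21 against 4 that fell, also over the list alone (set test adjusted p = 0.0014; adjusted p = 0.19 with an estimated correlation). The ligand Bmp4 went from 7.14 ± 0.880 to 34.2 ± 3.12 CPM and Id4 from 1.14 ± 0.27 to 5.48 ± 0.284 CPM. The BMP antagonist Grem1 fell from 2482 ± 49.3 to 613 ± 17.2 CPM, and Bmp7, under 1 CPM, fell as well (-2.05 ± 0.50). Of 19 tested Wnt target genes 12 rose and 4 fell, also over the list alone (set test adjusted p = 0.0067; adjusted p = 0.21 with an estimated correlation), led by the secreted Wnt modulator Sfrp2 (3.70 ± 0.12) and the feedback gene Nkd1 (1.66 ± 0.23). The Wnt-pathway transcription factors Tcf7 (-0.79 ± 0.18) and Lef1 (-1.37 ± 0.43, under 1 CPM in both groups) fell. Lef1 had no call when ZM sample 2 was left out (adjusted p = 0.061) or with DESeq2 (adjusted p = 0.077). Insulin-like growth factor genes and their binding proteins rose in 10 of 15 cases and fell in 2 (11 and 2 adjusted over the list alone; set test adjusted p = 5.8e-04; adjusted p = 0.19 with an estimated correlation), among them the protease Pappa2 (1.45 ± 0.04) and Igfbp3 (1.10 ± 0.06), with Igfbp6 (-0.93 ± 0.12) and Igf2r (-0.25 ± 0.03) lower. TGF-beta response and contractile genes fell in 13 of 24 cases and rose in 4 (13 and 5 adjusted over the list alone; set test adjusted p = 0.0046; adjusted p = 0.30 with an estimated correlation). Inhba (-1.08 ± 0.03) and periostin, Postn (-0.83 ± 0.04), fell, and Nox4 (0.98 ± 0.06) and Edn1 (0.90 ± 0.20) rose. Notch and Hedgehog targets, with 6 of 11 tested members higher and 2 lower, also over the list alone, did not pass the set test (adjusted p = 0.065) but passed fry (adjusted p = 6.08e-05). Gli2 (1.86 ± 0.20) and Notch3 (1.03 ± 0.07) rose, and Heyl (2.83-fold lower, under 1 CPM in both groups) and Hes1 (-0.38 ± 0.06) fell. That list passed without control sample 2 (adjusted p = 0.045) or control sample 3 (adjusted p = 0.048), and at a mean of at least 1 CPM (adjusted p = 0.0074).

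**Figure D2:**
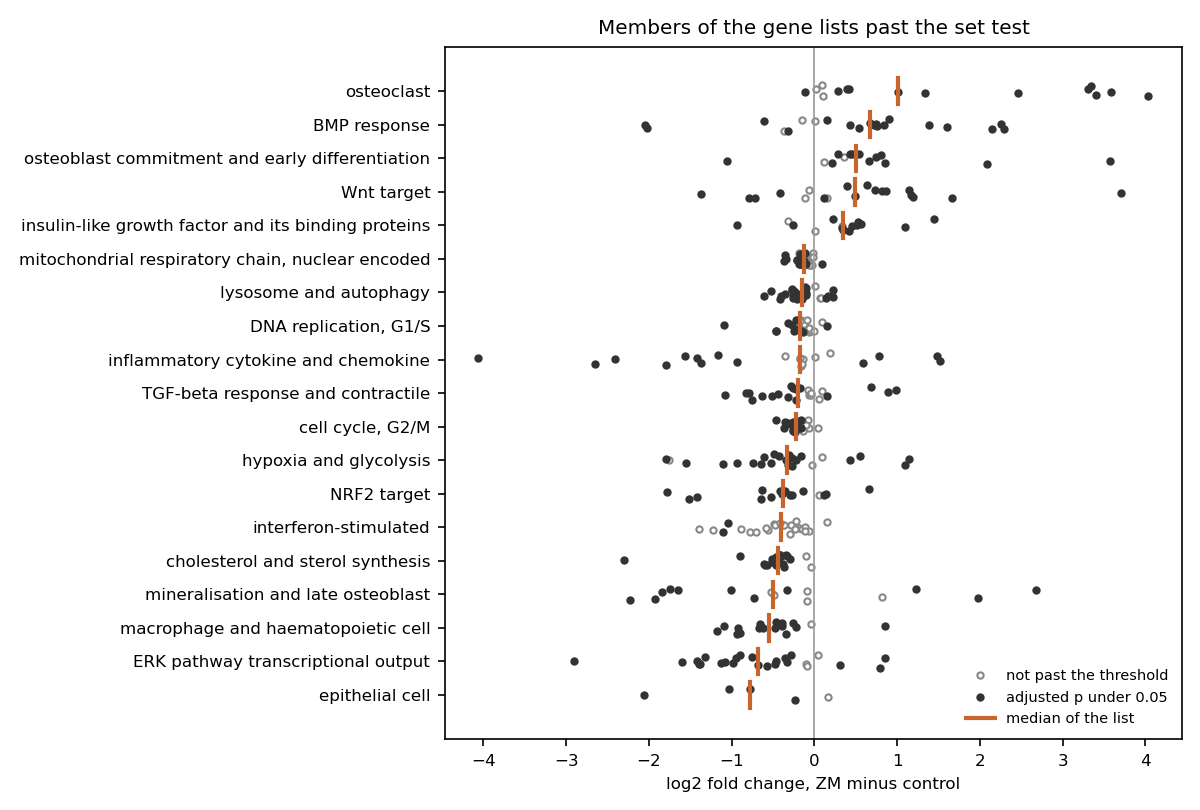
Log2 fold change (ZM minus control) of each tested member of the 19 gene lists past the set test, ordered by list median; filled points passed an adjusted p of 0.05, open points did not, and bars mark list medians. The osteoclast list has the highest median (1.01) and the cholesterol, macrophage and ERK lists lie mostly below 0.

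Proliferation genes were slightly lower. In the G2/M list 17 of 24 members fell and 0 rose (18 and 0 adjusted over the list alone; set test adjusted p = 3.9e-04; adjusted p = 0.38 with an estimated correlation), with Mki67 down from 169 ± 4.71 to 122 ± 6.69 CPM and Ccnb1 by 0.37 on the log2 scale. In the DNA replication list 12 of 24 fell and 1 rose (13 and 1 adjusted over the list alone; set test adjusted p = 0.0058; adjusted p = 0.38 with an estimated correlation), among them E2f2 (-1.09 ± 0.08) and Gins1 (-0.47 ± 0.12) against Rrm1 (0.16 ± 0.04). That list's call ended with DESeq2 (adjusted p = 0.088). Fewer members of both lists passed with scaling by library size alone, with 9 G2/M and 6 replication genes lower. Of 19 p53 targets 9 rose and 4 fell (10 and 5 adjusted over the list alone), including Trp53inp1 (0.85 ± 0.05), Fas (0.68 ± 0.05), Plk2 (-0.92 ± 0.04) and Gdf15 (-0.57 ± 0.15; adjusted p = 0.057 on FPKM). The list did not pass (set test adjusted p = 0.093) except without control sample 1 (adjusted p = 0.044) or without a filter on low counts (adjusted p = 0.019), and passed fry (adjusted p = 4.01e-04).

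Sterol synthesis genes fell together. Of 22 members 20 fell and 0 rose (21 and 0 adjusted over the list alone; set test adjusted p = 4.4e-11; adjusted p = 0.24 with an estimated correlation). The demethylase Cyp51 went from 368 ± 7.80 to 197 ± 2.05 CPM. Hypoxia and glycolysis genes fell in 17 of 24 cases and rose in 4, also over the list alone (set test adjusted p = 3.9e-04; adjusted p = 0.24 with an estimated correlation), with Ankrd37 (-1.54 ± 0.49) and Vegfa lower and Ndrg1 (1.14 ± 0.07) and Adm (1.09 ± 0.05) higher. Ankrd37 was under 1 CPM in both groups. Its call ended without control sample 1 (adjusted p = 0.056), ZM sample 1 (adjusted p = 0.051) or ZM sample 3 (adjusted p = 0.075), and with DESeq2 (adjusted p = 0.074). NRF2 targets fell in 12 of 16 tested cases and rose in 3, also over the list alone (set test adjusted p = 1.9e-04; adjusted p = 0.30 with an estimated correlation), including the cystine transporter Slc7a11 (-1.78 ± 0.18) and Gsta3 (-1.52 ± 0.07). Gsta4 (0.66 ± 0.16) and Gclc (0.14 ± 0.05) rose. Gclc had no call when control sample 2 (adjusted p = 0.094), control sample 3 (adjusted p = 0.17), ZM sample 1 (adjusted p = 0.087) or ZM sample 3 (adjusted p = 0.12) was left out. Nuclear-encoded respiratory chain genes fell in 13 of 27 cases and rose in 1, also over the list alone, with a median of -0.13 (set test adjusted p = 0.0042; adjusted p = 0.52 with an estimated correlation; adjusted p = 0.069 with DESeq2). With scaling by library size alone 6 were lower, and on FPKM 5. Cox5a fell by 0.36 and Cycs by 0.35 on the log2 scale. The riser was Sdha (0.09 ± 0.03), whose call ended without any sample except control sample 3 (adjusted p between 0.053 and 0.092) and without a filter on low counts (adjusted p = 0.063).

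The lists of aryl hydrocarbon receptor targets, unfolded protein and integrated stress genes, and dissociation and heat-shock genes did not pass camera, which compares a list with all other genes, while fry, which tests a list against no change, called each of them (adjusted p = 4.01e-04, adjusted p = 0.034 and adjusted p = 0.034). Aryl hydrocarbon receptor targets had 2 of 9 tested members higher and 4 lower (2 and 5 adjusted over the list alone; set test adjusted p = 0.16), with Cyp1b1 up from 284 ± 16.3 to 442 ± 5.75 CPM, Scin up (2.18 ± 0.32) and Nqo1 (-1.42 ± 0.05) and Nfe2l2 (-0.68 ± 0.06) down. Cyp1a1 had 4 counts in ZM sample 2 and 0 elsewhere. Unfolded protein and integrated stress genes had 6 of 24 higher and 11 lower, also over the list alone (set test adjusted p = 0.28), with Atf3 (0.99 ± 0.11) and Vldlr (0.67 ± 0.09) against Psat1 (-0.55 ± 0.05) and Pdia4 (-0.53 ± 0.03). Dissociation and heat-shock genes had 4 of 14 higher and 6 lower (4 and 7 adjusted over the list alone; set test adjusted p = 0.41), with Gadd45b (0.70 ± 0.06) higher and Socs3 (-0.81 ± 0.05) and Hspa1b (-0.73 ± 0.11) lower. Hspa1b matches other genes, mainly Hspa1a, over 78.5% of its transcript, so its reads may be split. Mitochondrially encoded transcripts made up 2.51% of counts in control and 2.93% in ZM libraries, which may be an undercount, since mt-Co1 and mt-Co3 match other annotated genes over 100% and 99.9% of their length and such reads may be missing. Of 13 such genes 4 rose, including mt-Nd5 (0.34 ± 0.04) and mt-Co1 (0.27 ± 0.04), and 2 fell, mt-Nd1 (-0.23 ± 0.03) and mt-Nd2 (-0.13 ± 0.04), also over the list alone (set test adjusted p = 0.79 with an upward direction, against a median and mean of -0.06). The mt-Nd2 call ended with scaling by library size alone (adjusted p = 0.12), on FPKM (adjusted p = 0.20), without control sample 2 (adjusted p = 0.058) and without ZM sample 1 (adjusted p = 0.065).

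Beside the macrophage and osteoclast lists above, epithelial genes were the only list of another cell type to pass camera. All 4 epithelial genes that passed fell, of 5 tested, also over the list alone (set test adjusted p = 0.038; adjusted p = 0.36 with an estimated correlation), with Cdh1 down from 2.93 ± 0.263 to 0.694 ± 0.111 CPM and Krt19 under 1 CPM in both groups (-1.04 ± 0.34). The list's call ended without control sample 1 (adjusted p = 0.097), without ZM sample 3 (adjusted p = 0.056), with DESeq2 (adjusted p = 0.12) and without a filter on low counts (adjusted p = 0.17). That of Krt19 ended without control sample 1 (adjusted p = 0.12), ZM sample 1 (adjusted p = 0.083) or ZM sample 2 (adjusted p = 0.053). Adipocyte genes had 7 of 17 higher and 8 lower (set test adjusted p = 0.64; fry adjusted p = 0.0010; 7 higher and 4 lower with scaling by library size alone), with the lipase Lpl up 7.04-fold and Zfp423 up (1.46 ± 0.16) against Fasn (-0.36 ± 0.04) and Cebpa (-0.35 ± 0.05). Chondrocyte genes had 6 of 13 higher and 2 lower (set test adjusted p = 0.15; fry adjusted p = 0.0023). Col9a2 (2.95 ± 0.44) and Col9a1 (1.92 ± 0.49) rose from under 0.1 CPM, and the lubricin gene Prg4 (-1.46 ± 0.07) and Col9a3 (-0.49 ± 0.19) fell. Col9a3 lost its call when control sample 2 or 3 or any ZM sample was left out (adjusted p between 0.051 and 0.16), and with a replicate block, DESeq2, library size alone or no filter (adjusted p between 0.058 and 0.13). Fibroblast, suture and tendon genes had 8 of 17 higher and 6 lower (set test adjusted p = 0.41; adjusted p = 0.012 with DESeq2; fry adjusted p = 4.90e-04), with tenomodulin, Tnmd (1.97 ± 0.07), and fibromodulin, Fmod (1.67 ± 0.04), higher and Pi16 (-1.85 ± 0.31) and Cd34 (-1.23 ± 0.10) lower. Pi16 was under 1 CPM in both groups. The adipocyte, chondrocyte and fibroblast lists gave the same counts adjusted over the list alone.

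Endothelial genes had 1 of 10 higher, Eng (0.68 ± 0.04), and 5 lower, and did not pass camera (set test adjusted p = 0.41). Among the lower were Cdh5 (-2.23 ± 0.37) and Esam (-1.34 ± 0.44), each under 1 CPM in both groups. Esam had no call when control sample 1 (adjusted p = 0.084), control sample 2 (adjusted p = 0.069), ZM sample 1 (adjusted p = 0.066) or ZM sample 3 (adjusted p = 0.066) was left out and with DESeq2 (adjusted p = 0.062). Pericyte and smooth muscle genes had 5 of 10 higher and 3 lower (6 and 4 adjusted over the list alone; set test adjusted p = 0.35; fry adjusted p = 0.0022), with Rgs5 (2.07 ± 0.14) and Mylk (2.83-fold) against Abcc9 (-2.05 ± 0.16) and Cspg4 (-1.66 ± 0.06). Skeletal muscle genes had 2 of 6 lower, Acta1 and Chrna1 (-1.96 ± 0.17), and 0 higher (set test adjusted p = 0.17; adjusted p = 0.022 with DESeq2; fry adjusted p = 5.17e-04). Schwann and neural genes had 2 of 10 higher, Map2 (1.83 ± 0.21) and Tubb3 (0.72 ± 0.06), and 2 lower, S100b (-0.66 ± 0.13) and Mbp (-0.16 ± 0.05), with a median of -0.04 and a mean of 0.17 (set test adjusted p = 0.78). Mbp lost its call without control sample 1 (adjusted p = 0.11), ZM sample 1 (adjusted p just above 0.05) or ZM sample 2 (adjusted p = 0.09), with scaling by library size alone (adjusted p = 0.15) and on FPKM (adjusted p = 0.21). The endothelial, muscle and neural counts were unchanged over the list alone. Of the haemoglobin and erythroid list 1 gene, Alas2, could be tested, at 0.251 and 0.166 CPM (adjusted p = 0.50).

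Among all genes above 5 FPKM whose groups did not overlap, the 12 largest rises were those of Sfrp2, Alpl, Mmp9, Acp5, Crispld2, Draxin, Lpl, Ogn, Mme, Ism1, Nid2 and Ccn3, with log2 fold changes from 3.70 to 2.45. The basement membrane protein nidogen 2, Nid2, was the most abundant of them after treatment, at 169 ± 8.40 CPM in control and 935 ± 42.0 CPM in ZM samples. The small proteoglycan osteoglycin, Ogn, went from 13.9 ± 1.08 to 96.4 ± 4.90 CPM, the axon guidance gene Draxin from 4.50 ± 0.617 to 33.2 ± 1.89 CPM, and the stromal peptidase Mme from 13.3 ± 0.666 to 83.4 ± 7.37 CPM. Crispld2 rose 7.56-fold, Ism1 5.60-fold and Ccn3 5.48-fold.

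The 12 largest falls were those of Mmp10, Il1a, Serpinb2, Pf4, Il1rl1, Sema7a, Crabp1, Acta1, Prl2c2, Has2, Lif and Slco4a1, with log2 fold changes from -4.88 to -2.80. Il1a, a cytokine of the interleukin 1 family, went from 30.0 ± 6.38 to 1.30 ± 0.346 CPM, and Il1rl1, the receptor for interleukin 33, from 265 ± 15.5 to 29.0 ± 2.25 CPM. The platelet factor gene Pf4, which macrophages also express, went from 172 ± 16.8 to 17.1 ± 1.08 CPM, and the plasminogen activator inhibitor Serpinb2 from 81.4 ± 7.78 to 5.26 ± 0.874 CPM. The hyaluronan synthase Has2 went from 137 ± 9.76 to 18.6 ± 0.944 CPM and the semaphorin Sema7a from 81.7 ± 6.36 to 9.02 ± 1.04 CPM. Crabp1 was 8.84-fold, Acta1 7.80-fold and Slco4a1 6.95-fold lower. The 7.42-fold fall of Prl2c2 is uncertain, since its transcript matches Prl2c3 over 100% of its length. The levels of further genes named above are uncertain in part. Their exons overlap another annotated gene over 26.4% of their length for Ankrd37, 24.4% for Spry1, 18.8% for Spp1, 16.1% for Sfrp2, 15.5% for Alas2, 13.8% for Lef1, 12.8% for Cox5a, 12.4% for Serpinb2, 11.6% for Loxl3 and 11.3% for Il1a. The transcripts of Ccnb1 and Cycs match other annotated genes over 52.0% and 33.7% of their length.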

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

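The alternatives were set before the data were examined. The number of changed genes was 7032 with DESeq2, 7943 with RLE size factors, 8100 with library size alone, 8031 without a filter, 7342 at a mean of at least 1 CPM and 6308 by limma on log2(FPKM + 1), where fewer genes were tested. Leaving out 1 sample gave 6813 to 7712 genes and 16 to 20 lists. On FPKM 2348 genes were lower, against 3935, and with library size alone, the scaling that FPKM values hold, 3059 were. Scaling thus moved the count the same way, and the rest of the difference was not tested. By construction a minimum fold gave fewer genes, 1329 (582 higher, 747 lower) at 2-fold and 1318 (619 higher, 699 lower) with glmTreat. Of the 19 lists, 0 passed with an estimated correlation. Correlation between members cannot be the whole cause. The estimate was below 0 for the ERK (-0.019), BMP (-0.041), mineralisation (-0.040) and insulin-like growth factor (-0.042) lists, which lost their calls too. A call lost in this setting therefore does not show that the members of that list vary together. What else lowered the calls was not tested. Fry called 30 lists, 18 of them in common (interferon-stimulated genes lost). DESeq2 kept 15 and added EGF, skeletal muscle and fibroblast genes, no filter kept 18 and added p53 targets, and a mean of at least 1 CPM kept 17 and added Notch and Hedgehog targets. FPKM also kept 17 and added 0. RLE size factors kept 18. At a mean of at least 1 CPM and on FPKM the inflammatory list lost its call and the epithelial list had too few tested members.

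No sign was found that equal sample numbers pair the samples, but the labels do not say and so few samples cannot exclude it. The deviations of equal-numbered samples from their group means correlated at -0.04, 0.06 and -0.01, against -0.08 to 0.09 for unequal numbers. Not every sample correlated best with its own number. With a replicate block 7752 genes changed and 7594 of the 7939 calls were kept.

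Directions reversed only where no call was made. For Col1a1 the log2 fold change was 0.040 with library size alone, 0.041 on FPKM and -0.043 to 0.013 with 1 sample left out, above 0 without control sample 3. In the set tests the direction reversed, with the mean log2 fold change given, for matrix proteases (-0.032) and adipocyte genes (0.22) on FPKM, VEGF genes with DESeq2 (-0.036) and fry (-0.032), osteocyte genes (-0.14) and regulators of osteoclasts (-0.20) with fry, and mitochondrially encoded transcripts with the replicate block (-0.047) and without control sample 2 or ZM sample 3 (-0.14 to 0.047 over the samples left out). The cause was not tested. Of 162 named genes, 147 kept direction and side of the threshold under every alternative that gave them a value. Little can be said of Ibsp, Bglap and Dmp1, with at most 14 counts in a library, and for Bglap shared reads may be missing.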

Other observations

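The lists in the first paragraph, and all tests in this part except the splits of the samples, were chosen after the values were seen, so they are not independent evidence. The same holds for the genes Lyz2, Csf1r, Ptprc, Trem2, C1qa, C1qb, C1qc, Calcr, Oscar, Ctsk and Gapdh, which were also named after their values were seen. Set test p-values of the added lists were adjusted over these 3 lists alone. Those of the lists written beforehand were adjusted over all lists tested there. The adjusted p-values of the added lists therefore cannot be compared directly with those given above, with or without an estimated correlation. Receptors by which myeloid cells sense microbes and damage were lower with ZM: 26 of 30 fell and 1 rose, Tlr13 (log2 fold change 0.28 ± 0.04, SE), with adjusted p = 1.05e-14 in camera and adjusted p = 0.0072 with an estimated correlation. The sialic acid receptor Siglec1 went from 346 ± 19.6 to 74.6 ± 1.32 CPM (SD, n = 3 each) and the oxidised lipid receptor Olr1 from 42.7 ± 5.16 to 6.67 ± 0.822 CPM. Small leucine-rich proteoglycans, which bind collagen fibrils, rose in 8 of 16 tested cases and fell in 3 (adjusted p = 0.0037; adjusted p = 0.063 with an estimated correlation), including Prelp, from 111 ± 10.3 to 590 ± 34.2 CPM, and Fmod, from 369 ± 15.6 to 1175 ± 37.4 CPM. Complement genes rose in 9 of 20 tested cases and fell in 4 (adjusted p = 0.0052; adjusted p = 0.26 with an estimated correlation). This list left out C1qa, C1qb and C1qc, which are in the macrophage list and fell. It counted among the rises C1qtnf1, a C1q-related gene with 20.5% of its exon bases in another gene. The upward call may thus depend on the choice of members, which was not tested. The proteases C1ra and C1s1 (uncertain, since C1ra matches C1rb over 81.5% of its transcript and C1s1 exons overlap another gene over 18.4%) and the inhibitor Serping1 rose 2.13 to 2.35-fold, while Cfp and C5ar1, which myeloid cells express, fell.

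For the number of changed genes, the real grouping gave 7939 and the highest of the other splits gave 0. Only 1 of the 10 splits of the 6 samples into 3 and 3 gave as many, but 10 splits are too few for a share under 0.05.

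Macrophage markers were lower in all ZM libraries. A lower share of 1 uniform macrophage population that alone made these markers would lower each by the same fold. The values argue against that narrow case: over the 17 list members with at least 10 CPM the SD of the log2 fold changes was 0.45, against a median standard error of 0.05. Markers also made by other cells, or a changed mix of myeloid cells, would give unequal folds from shares alone. Unequal folds therefore cannot exclude a change of share as the whole change. The list's most abundant gene, Lyz2, went from 16444 to 8668 CPM (log2 fold change -0.92). Csf1r (-0.34, with 15.1% of its exon bases in another gene) and Ptprc (-0.22) fell less, and Trem2 (-0.04) did not pass. Of the list's tested genes 0 are in another list. A lower share as part or all of the change stays open, since 15 of the 17 members fell and only 1, Cx3cr1, rose. No value here separates fewer macrophages from macrophages with less of these transcripts. An effect of ZM within the myeloid cells was not tested.

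Osteoclast genes rose in cultures where macrophage markers were lower. Osteoclasts carried into 1 ZM sample are argued against, since over all 15 tested members the mean log2 CPM of the lowest ZM library lay 1.42 above that of the highest control library, against a largest SD within a group of 0.09. A higher share of osteoclast-lineage cells stays open: among the 13 members with at least 1 CPM the median log2 fold change was 0.42, 9 rose and 1 fell. The restricted genes Dcstamp (0.348 to 5.86 CPM) and Oscar (0.882 to 5.03 CPM) rose far more than Ctsk (0.42, from 434 to 582 CPM), but from low levels. So did Calcr (0.094 to 0.910 CPM), which is near the floor and not among the 13. Ctsk is the most abundant of the list, and other cells of the culture may also express it (2 tested members, Mmp9 and Ctsk, are also in the protease list). Whether more precursors fused or existing cells made more of these transcripts cannot be told from bulk counts. An effect of ZM through the higher Tnfsf11 level was not tested.

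Osteoblast commitment genes and mineralisation genes moved apart. A higher share of 1 uniform osteoblast-lineage population that alone made these transcripts would raise both lists alike. Over 18 members with at least 10 CPM the SD of the log2 fold changes was 1.40, against a median standard error of 0.05, with 9 higher and 7 lower. These values go against that narrow case only, and the lists had already been seen to move apart. Macrophages also make Spp1, for one, so the values cannot exclude a change of share as the whole change. An effect of ZM within the cells and a change in which osteoblast-lineage cells were present were not tested.

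Interferon-stimulated genes varied widely within the ZM group. The mean log2 CPM of the list, relative to the mean of all 6 libraries, was 0.57 in ZM sample 2 against -0.83 and -0.71 in ZM samples 1 and 3, and 0.58, 0.29 and 0.10 in control samples 1 to 3. The Gapdh count was 5949 in control sample 3 and 315 to 1128 in the other 5 samples. Its transcript matches those of 97 other annotated genes in part. Gapdh is a tested member of the hypoxia and glycolysis list, so its part in that list's result is uncertain.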
